A study of Mus musculus with 2 samples.

How the data were processed

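Droplet single-cell RNA sequencing of whole mouse uterus was analysed in 2 libraries, 1 labelled as control and 1 from Rest f/f mice with PR-Cre (cKO), each from the pooled tissue of 2 animals. The names of the deposited data add Rest f/f for the control, and its Cre status is not stated. Per the labels, the deposited values are raw UMI counts made with Cell Ranger 5.0.1 and the GRCm38 (mm10) reference; whether intronic reads were counted is not stated. The deposited matrices hold 32285 genes and 6794880 barcodes per library, including empty droplets, and were checked to contain whole numbers only. No column belonged to a sample without a group. Everything else was computed from these counts.

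The control library held 74336022 UMIs in 1288347 barcodes and the cKO library 102880666 UMIs in 1467416 barcodes. A barcode was kept as a cell with at least 1000 UMIs, at least 500 genes and at most 20% of UMIs from mitochondrial genes. The number of barcodes with at least 1000 UMIs was 5434 in the control and 8760 in the cKO library, of which 4681 and 6986 passed the gene minimum and 4327 and 6116 the mitochondrial limit. Doublets were scored by the share of simulated doublets among the neighbors of a cell, and the highest scores, 0.8% per 1000 cells, were removed (150 control and 299 cKO barcodes), which left 4177 and 5817 cells with 56432123 and 71526800 UMIs. Tested on simulated data, that step placed 84 of 200 simulated doublets among the 200 highest scores, so doublets remain. Barcodes of 1 to 100 UMIs served as the profile of free RNA.

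Both libraries were clustered together: counts were scaled to the total of each cell and log-transformed, 2000 variable genes were reduced to 30 principal components, and a graph of 15 nearest neighbors was divided by the Leiden algorithm at resolution 1 with seed 1. No batch correction was applied, because library and genotype coincide. Clusters were named by 17 sets of marker genes, and every name means resemblance to a cell type by those markers. A cluster stayed unnamed when fewer than 3 markers were detected, when markers of another class prevailed among its 10 leading genes, when a second class scored at least 0.6 of the highest score, or when its cells were shallow and no marker led it. These naming thresholds were set after the clusters were seen. Of 27 clusters 3 were unnamed, with 5.29% of the control and 5.21% of the cKO cells. Clusters made almost wholly of 1 library may reflect that library rather than a cell type.

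UMIs were summed over the cells of each class and library and expressed as counts-per-million (CPM) of the class total. Log2 ratios, cKO over control, were taken after adding 10 CPM. The 6 classes with at least 100 cells in both libraries were compared: smooth muscle-like, stromal-like, epithelial-like, T/NK-like, dendritic-like and macrophage-like. Their summed UMIs ran from 1362195 (smooth muscle-like, cKO) to 33063308 (stromal-like, control). With 1 library per group no test between genotypes was run. Shares have exact Clopper-Pearson intervals, levels exact Poisson intervals, and ratios exact conditional binomial intervals, all at 95%. Against 0 UMIs a fold is a lower bound from 3 counts over the class in that library. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, beside the unthinned shares.

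The 23 gene lists were REST-repressed neuronal, uterine leiomyoma, fibrillar and matrix, basement membrane, contractile, parturition and excitability, progesterone-responsive, estrogen-responsive, hormone receptor, luminal epithelium, glandular epithelium, TGF-beta response, Wnt pathway, cell cycle, immediate early, heat shock, interferon response, MHC class II, hypoxia and glycolysis, chemokine and cytokine, mitochondrially encoded, hemoglobin, and neuronal and glial genes. They were written from general knowledge; some share members, as the REST-repressed and leiomyoma lists do, and most contractile genes are also smooth muscle markers. A member counted as measured with at least 10 UMIs in the class. For each list the median log2 ratio, the members at least 1.5-fold higher or lower, and the percentile of the median among 10000 random lists matched over 20 bins of mean expression are given, as a description of these libraries. Ccl21a and Aldoa each name 2 genes and were left out. The general shift of a class is the median log2 ratio over genes with at least 50 CPM in either library, and centred values subtract it.

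Genes named in the text were chosen by rule: at least 50 CPM in either library, at least 30 UMIs over both, and a level of at least 25% of the highest over the compared classes of that library, which guards against free RNA. The 10 highest and 10 lowest log2 ratios were named in the smooth muscle-like, stromal-like and epithelial-like classes and the 5 highest and 5 lowest in the other classes, without mitochondrial, ribosomal, hemoglobin, unnamed and X-inactivation genes. Rest, Pgr, Esr1 and Prlhr, and up to 2 members from each end of a list, were added. Of the genes so chosen, 2 are not reported here. The lists, the markers, the naming rule for genes, the filters, the statistics and most alternative settings were fixed before the data were examined. The other alternatives were added later. Alternatives varied the cell filters, doublet removal, clustering, denominator of shares, scaling, free RNA subtraction, pseudocount and list minimum.

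Tested on simulated libraries of the depth of the smooth muscle-like, epithelial-like and stromal-like classes, with 200 of 3681 genes changed, the ratio interval held the true ratio for 95.5% of genes at the smooth muscle-like depth and 96.0% or more at the other depths. At the smooth muscle-like depth 14 of 25 genes simulated as 8-fold lower and 23 of 25 simulated as 1.5-fold higher came within 0.2 of their log2 ratio, and at the other depths all 25 did; the depths of the immune classes were not simulated. Gene positions are those of GENCODE M21 on GRCm38, matched by identifier. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used.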

Results

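Whole uteri of 5-month-old mice were profiled by droplet single-cell RNA sequencing with 3′ tags, in which every mRNA molecule is counted by its unique molecular identifier (UMI). One library, called cKO here, came from Rest f/f mice with PR-Cre, and the other is labelled as control, with Rest f/f only in the names of its deposited data; whether its animals lacked Cre is not stated. Each of the 2 libraries pooled the tissue of 2 animals. Rest encodes REST, a repressor that keeps neuronal genes silent outside neurons, and PR-Cre is a Cre recombinase knocked into the progesterone receptor gene Pgr (general background, not in the labels). The series title links loss of REST to progesterone receptor function and to leiomyoma, the benign tumor of uterine smooth muscle, and the comparison asks how the cell classes of a uterus without REST in Pgr-expressing lineages differ from the control. With 1 library per group no difference between genotypes can be tested, so the values describe these libraries. The 95% intervals in brackets cover counting error only. Genes called highest or lowest in a class are so by log2 ratio with 10 CPM (counts-per-million of the UMIs of the class) added to each level, among genes that reach 50 CPM.

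The control library held 74336022 UMIs and the cKO library 102880666. After filtering, 4177 control cells and 5817 cKO cells were kept, with medians of 8491 and 5425 UMIs and of 2771 and 2096 genes per cell. Mitochondrial genes supplied a median of 3.77% of the UMIs of a control cell and 4.30% of those of a cKO cell. Barcodes of 1 to 100 UMIs, taken as free RNA, held 6.36% of all control UMIs and 5.23% of all cKO UMIs. Clustering of both libraries together gave 27 clusters, 24 of which were named by marker genes into smooth muscle-like, stromal-like (fibroblast), epithelial-like, endothelial-like, pericyte-like, mesothelial-like and immune classes.

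Rest itself (ENSMUSG00000029249, GRCm38 chromosome 5, 77265491 to 77286432) was detected in both libraries in every compared class. Its level in the smooth muscle-like class was 212 CPM in the control and 179 in the cKO library, a ratio of 0.846 [0.727, 0.982], while its log2 ratio relative to the general shift of that class (-0.40, the median log2 ratio of well-expressed genes) was 0.17. In the stromal-like class Rest stood at 140 CPM in the control and 195 in the cKO library (ratio 1.39 [1.34, 1.45]), and in the epithelial-like class at 95.1 and 122 CPM (ratio 1.28 [1.17, 1.40]). Inside stromal-like clusters the Rest ratio was 0.998 [0.933, 1.07] in cluster 1, 1.70 [1.14, 2.61] in cluster 4, 1.82 [1.51, 2.19] in cluster 6 and 1.97 [1.43, 2.65] in cluster 14. T/NK-like cells, in which PR-Cre is not known to act, held 110 and 112 CPM of Rest. After every cell was thinned to 1000 UMIs, a Rest UMI was found in 14.4% of control and 11.9% of cKO smooth muscle-like cells. The corresponding shares were 14.6% and 17.6% in the stromal-like class and 7.53% and 11.6% in the epithelial-like class. The labels do not describe the deleted part of Rest, and a 3′ tag outside it is still counted from a recombined allele, so the Rest level does not check the genotype.

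Smooth muscle-like cells made up 18.2% [17.0, 19.4] of the control cells (759 cells) and 10.4% [9.59, 11.2] of the cKO cells (603). Macrophage-like or monocyte-like cells made up 8.16% [7.35, 9.04] of the control and 13.0% [12.1, 13.9] of the cKO library. Neutrophil-like cells numbered 11 in the control (0.263% [0.132, 0.471]) and 408 in the cKO library (7.01% [6.37, 7.70]). All immune classes together held 26.4% [25.1, 27.8] of the control and 35.9% [34.7, 37.1] of the cKO cells. Stromal-like cells took 35.5% [34.1, 37.0] and 32.8% [31.6, 34.1], and epithelial-like cells 11.1% [10.2, 12.1] and 11.8% [11.0, 12.7]. Among non-immune cells alone, the smooth muscle-like share was 24.7% in the control and 16.2% in the cKO library, while the stromal-like share was 48.3% and 51.2%. Shares sum to a whole and follow tissue digestion as well as the tissue, and the smooth muscle-like difference of -7.80 percentage points was -0.046 when cells down to 500 UMIs and 250 genes were kept, a setting that left 24.7% of the control and 15.7% of the cKO cells unnamed and 508 control cells in that class. The macrophage-like and stromal-like differences changed sign when each library was clustered alone, to -3.07 and 13.8 points, with 20.7% of the control and 13.4% of the cKO cells unnamed.

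**Figure D1:**
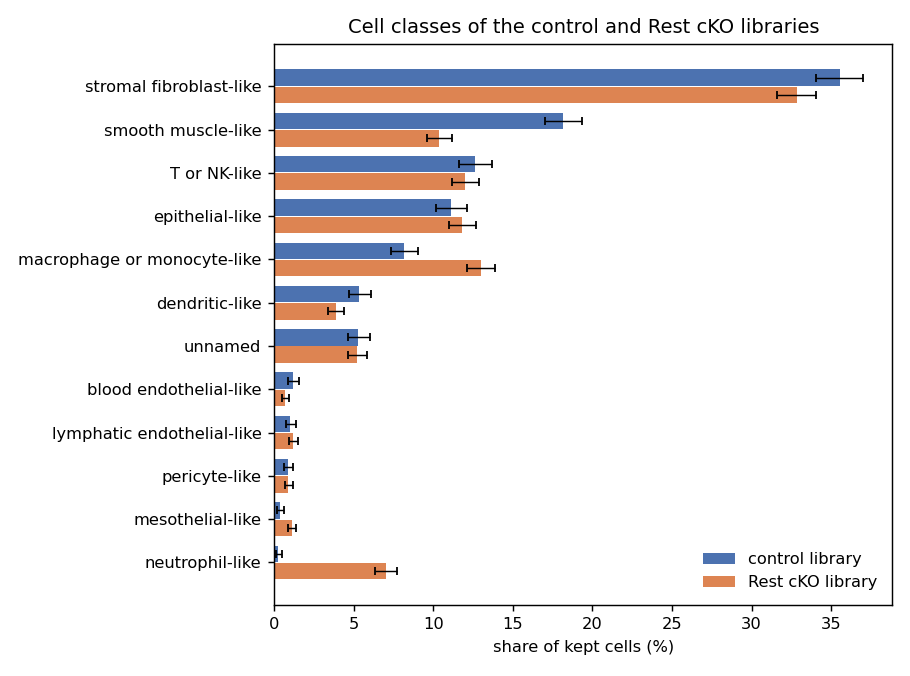
Share of kept cells (percent, horizontal axis) in each cell class (vertical axis) in the control and the cKO library, with exact 95% intervals for counting error. The smooth muscle-like share is 18.2% in the control and 10.4% in the cKO library, and the neutrophil-like share 0.263% and 7.01%.

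Genes repressed by REST in non-neuronal tissue had the highest median ratio of all lists in the stromal-like and smooth muscle-like classes. Of a fixed list of 45 such genes, 42 were measured in the stromal-like class, and 39 of them were at least 1.5-fold higher in the cKO library with 0 lower. Their median log2 ratio was 1.51, above all 10000 random lists matched on expression (percentile 100), and 1.63 relative to the general shift of the class. Their summed level was 63.6 CPM in the control and 3056 CPM in the cKO library. In the smooth muscle-like class 30 of 33 measured genes were higher and 0 lower, with a median log2 ratio of 1.57 (percentile 100, centred value 1.97) and sums of 147 and 1849 CPM. The epithelial-like class had 30 of 33 higher and 0 lower, a median of 0.95 (percentile 100) and sums of 67.2 and 1032 CPM. With the members that had 0 control UMIs set to the bound of 3 counts, the medians were 1.51, 1.57 and 0.89 in the stromal-like, smooth muscle-like and epithelial-like classes. In each of the 9 clusters of these classes with at least 30 cells in both libraries, the list was higher as well: in the smooth muscle-like cluster 0, for example, 32 of 32 measured genes were at least 1.5-fold higher, with sums of 60.1 and 1716 CPM.

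Immune classes gave smaller values. In the macrophage-like class 18 of 20 measured genes were higher and 1 was lower, with a median of 0.32 (0.25 with zeros at the bound, percentile 100) and sums of 10.7 and 69.2 CPM. T/NK-like cells had 7 of 10 higher and 1 lower, with a median of 0.26 (0.21 at the bound, percentile 99.98), and dendritic-like cells 3 of 3 higher, with a median of 0.44 (percentile 98.8). Free RNA carried the list too, at 69.2 CPM in the control and 1171 CPM in the cKO library.

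The synaptotagmin gene Syt4 (ENSMUSG00000024261, chromosome 18, 31437808 to 31447406) shows the contrast per cell. After thinning to 1000 UMIs, 0 of 1484 control stromal-like cells held a Syt4 UMI, against 620 of 1910 cKO cells (32.5% [30.4, 34.6]). The 0 describes that depth and not an absence of Syt4, since without thinning the shares were 1.62% and 66.4%, at median depths of 21163 and 16860 UMIs. In smooth muscle-like cells the shares were 0 of 759 and 12.9% [10.4, 15.9] after thinning, and 0.132% and 20.2% without it. T/NK-like cells, which should lack Syt4, gave 0 of 528 in the control and 0.716% in the cKO library, as a measure of background. Scg2, a secretogranin gene, was found in 0 control and 8.80% of cKO thinned stromal-like cells, and Scg3 in 0.135% and 10.9%.

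**Figure D2:**
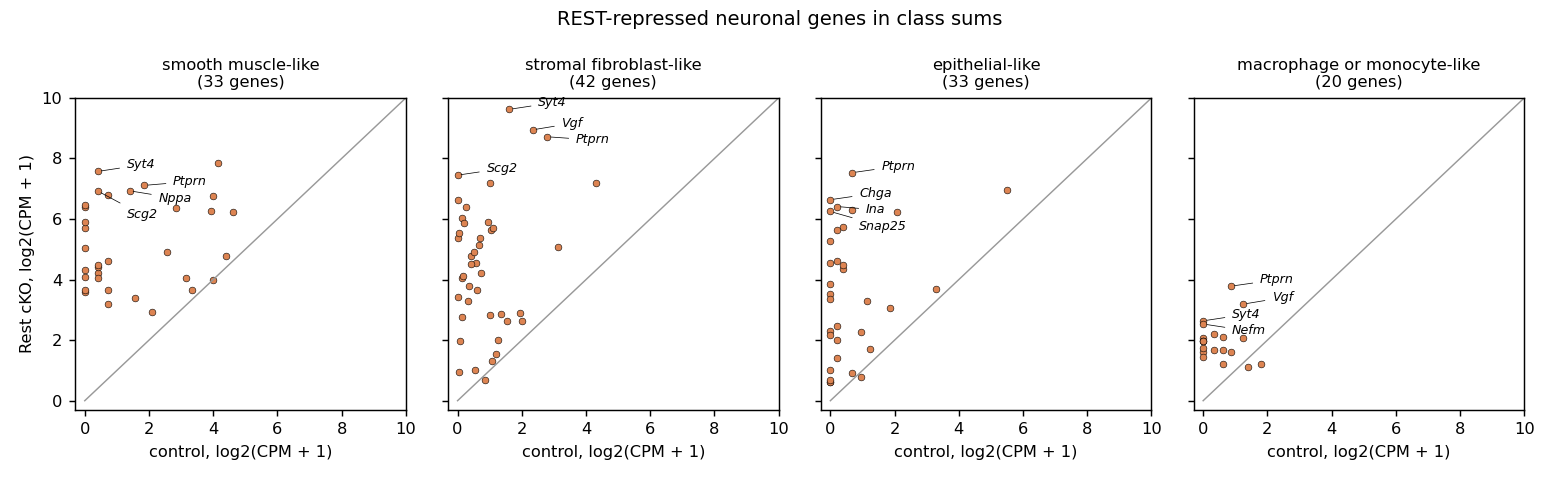
Level of each measured gene of the REST-repressed list in the control (horizontal axis) and the cKO library (vertical axis), both as log2(CPM + 1), in the smooth muscle-like, stromal-like, epithelial-like and macrophage-like classes; the line marks equality. Most points lie above the line in each panel, with 39 of 42 genes at least 1.5-fold higher in the stromal-like class.

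In the stromal-like class, secretory granule and synaptic genes of that list (Syt4, Vgf, Ptprn, Scg2, Snap25 and Scg3) also made up most of the 10 genes with the highest ratios. Syt4 stood at 2.06 CPM in the control and 788 CPM in the cKO library, a ratio of 383 [302, 493]. Vgf, a neuropeptide precursor gene (ENSMUSG00000037428, chromosome 5, 137026392 to 137033351), stood at 4.05 and 492 CPM (ratio 121 [102, 145]). Ptprn, which encodes a dense-core vesicle protein (ENSMUSG00000026204, chromosome 1, 75247027 to 75264502), stood at 5.90 and 420 CPM (ratio 71.2 [61.8, 82.5]). Scg2 (ENSMUSG00000050711, chromosome 1, 79434669 to 79440120) had 0 UMIs in the control and 174 CPM in the cKO library, at least 1915-fold higher, and Snap25 had 0 and 98.1 CPM, at least 1082-fold higher. Sez6l2 stood at 0.212 and 141 CPM (ratio 665 [323, 1656]), Scg3 at 1.03 and 144 CPM, and Crmp1 at 1.18 and 148 CPM. Lrp11 was at 2.09 and 119 CPM, and Crtac1, of cartilage acidic protein, at 3.12 and 138 CPM.

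The lowest ratios of the stromal-like class belonged to genes of varied function. Igfbp3, which encodes an IGF-binding protein (ENSMUSG00000020427, chromosome 11, 7206086 to 7213923), had 774 CPM in the control and 153 CPM in the cKO library, 5.08-fold lower [4.93, 5.24]. The chemokine gene Cxcl5 had 514 and 98.7 CPM (5.21-fold lower [5.01, 5.41]) and the carboxylesterase gene Ces1d 81.3 and 12.4 CPM (6.56-fold lower [5.91, 7.31]). Phgdh was 3.39-fold lower, Mmp3 and Clec3b were both 2.99-fold lower, Fst 2.88-fold, Ctla2a 2.81-fold and Ccl2 2.76-fold lower. Several of these genes also help to define clusters that belong mostly to 1 library: Syt4 and Scg2 lead cluster 5 (4 control and 540 cKO cells), Crtac1 leads cluster 7 (10 and 450), Crmp1 cluster 4 (79 and 503), Clec3b cluster 6 (421 and 43) and Phgdh cluster 14 (261 and 31), while Igfbp3 and Mmp3 lead cluster 1 (709 and 343). Clusters 1, 6 and 14 held 45.0%, 28.9% and 24.4% of the control UMIs of the class, and clusters 5, 7 and 1 held 40.0%, 32.2% and 20.6% of the cKO UMIs. Inside cluster 1, Syt4 stood at 3.43 and 818 CPM (ratio 239 [181, 321]) and Igfbp3 at 1373 and 484 CPM (ratio 0.353 [0.340, 0.366]), but Ctla2a was higher in the cKO library there, with a log2 ratio of 1.20. Cxcl5, Ccl2 and Cxcl2 were higher in the cKO library in the clusters with more Hand2, a transcription factor of endometrial stroma, with log2 ratios of 2.55, 1.03 and 0.41.

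Of the matrix genes 13 of 29 were at least 1.5-fold higher and 4 lower in the cKO stromal-like class, with a median log2 ratio of 0.43 (percentile 100), or 0.56 relative to the general shift, and sums of 24411 and 35589 CPM. The collagen genes Col6a2 (920 and 2553 CPM) and Col6a3 (984 and 2488 CPM) had the highest ratios, and Has2 (330 and 122 CPM) and Postn (547 and 263 CPM) the lowest. Inside clusters the matrix median was 0.024 in cluster 1, -0.15 in cluster 6, -0.51 in cluster 14 and 1.20 in cluster 4 (21 of 27 higher, 2 lower). Of these clusters only cluster 4 showed the higher class value, and how far that value follows the mix of clusters was not tested. Interferon response genes had 13 of 16 higher and 1 lower, a median of 0.50 (percentile 100) and 0.63 relative to the shift; Bst2 stood at 86.7 and 323 CPM and Ifi27l2a at 46.0 and 102 CPM. Inside clusters that median was 0.14 in cluster 1, 0.012 in cluster 6, 1.51 in cluster 4 and 1.57 in cluster 14. Mitochondrially encoded genes, a sign of damaged cells, had medians of 0.29, 0.45, 0.64 and 0.81 in clusters 1, 6, 4 and 14. Chemokine and cytokine genes split, with 7 of 20 higher and 11 lower and a median of -0.22 (percentile 0.88, -0.09 relative to the shift): Ccl11 (42.3 and 328 CPM) and Ccl8 (10.3 and 73.5 CPM) were higher, Cxcl5 and Cxcl2 (547 and 103 CPM) lower. Inside clusters 1, 4, 6 and 14 that median was -0.021, 0.079, 0.30 and 0.098, so the lower class value was not found inside most of them. Ccl11 was lower in the cKO library in the clusters with little Hand2, with a log2 ratio of -0.26. Progesterone-responsive genes had 4 of 24 higher and 9 lower, a median of -0.09 (percentile 3.21), which became 0.03 relative to the shift. Among them Wnt4 was at 112 and 46.2 CPM, Fst at 640 and 222 CPM, and Bmp2 at 32.0 and 94.3 CPM, and the median was -0.070, 0.16, -0.15 and -0.26 inside the same clusters. Wnt pathway genes had a median of -0.18 (2 of 18 higher, 7 lower, percentile 0.49; -0.06 relative to the shift), with Wnt5a at 76.7 and 189 CPM, and -0.051, 0.17, 0.060 and 0.20 inside those clusters. With each library clustered alone the log2 ratio of Wnt4 was 0.16 and the median of the Wnt list 0.018. Among these list members Ccl11 and Wnt5a lead cluster 7, Ccl11 also cluster 4, Wnt4 cluster 14 and Has2 cluster 6. Their class values may follow the sizes of those clusters, which was not tested. The general shift was -0.12 in this class, 0.041 in the epithelial-like class and between -0.025 and 0.026 in the immune classes.

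Smooth muscle-like cells fell into clusters 0 (519 control and 572 cKO cells) and 17 (240 and 31). Cluster 17 held 70.7% of the control UMIs of the class but 14.3% of the cKO UMIs, so class values mix a difference of composition with differences inside clusters. With 10 CPM added to each level, the highest log2 ratio of the class belonged to Acta1, skeletal muscle alpha-actin (ENSMUSG00000031972, chromosome 8, 123891769 to 123894751), at 9.46 CPM in the control and 570 CPM in the cKO library (ratio 60.3 [41.6, 90.6]). It was followed by neuronal genes and the natriuretic peptide gene Nppa, at 1.63 and 121 CPM (ratio 74.3 [31.2, 232]). Syndig1l, Ina and Snap25 had 0 control UMIs and were at least 141-fold, 88.5-fold and 84.8-fold higher. Scg2 was at 0.326 and 120 CPM, Ptprn at 2.61 and 137 CPM (ratio 52.6 [26.1, 124]), Vgf at 16.6 and 231 CPM (ratio 13.9 [10.3, 19.1]), Stmn3 at 0.652 and 109 CPM (ratio 168 [45.6, 1397]) and Crmp1 at 1.30 and 83.0 CPM. Acta1 leads cluster 0, and inside that cluster it stood at 12.2 and 651 CPM.

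The lowest ratios of the smooth muscle-like class belonged to Flrt1, which leads cluster 17 (421 and 23.5 CPM, 17.9-fold lower [12.6, 26.3]), to the hormone-responsive genes Greb1 (764 and 107 CPM, 7.13-fold lower [6.03, 8.49]) and Inhbb (1783 and 295 CPM, 6.04-fold lower [5.46, 6.70]), and to the noncoding RNA genes Kcnq1ot1 (1051 and 105 CPM) and Carmn (118 and 11.0 CPM). Relt was 12.5-fold lower, Per2 7.80-fold, Rai1 7.18-fold, Fubp1 5.86-fold and Zmiz1 5.35-fold lower. Inside cluster 0 the ratio of Flrt1 was 0.209, that of Greb1 0.506 [0.373, 0.684] and that of Inhbb 0.313 [0.266, 0.367], while Kcnq1ot1 (14 and 31 UMIs) and Carmn (2 and 3 UMIs) were too sparse there for a direction. Inside cluster 17, which held most of their control UMIs, the ratio of Kcnq1ot1 was 0.389 [0.320, 0.470] and that of Carmn 0.373 [0.191, 0.660], with 0.145 for Flrt1, 0.355 for Greb1 and 0.412 for Inhbb.

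Contractile genes, many of which lead cluster 0, had 16 of 20 members higher and 0 lower in the cKO smooth muscle-like class, with a median log2 ratio of 1.06 (percentile 100), 1.46 relative to the shift. Myl9 stood at 465 and 2678 CPM and Actg2 at 390 and 2218 CPM, while Myocd (71.1 and 59.5 CPM) and Smtn (452 and 426 CPM) differed little. Inside cluster 0 the median was 0.63, with 12 higher and 0 lower, and inside cluster 17 it was 0.43, with 8 higher and 0 lower. Genes described as raised in human leiomyoma had 4 of 14 higher and 3 lower in the class and a median of -0.04 (percentile 68.2), or 0.36 relative to the shift. Inside cluster 0, 7 of the 9 measured were higher and 1 lower, with a median of 0.96: Ccnd1 (cyclin D1) stood at 13.7 and 120 CPM in the class and had a ratio of 6.28 in cluster 0, and Pcp4, itself a leading gene of cluster 0, stood at 989 and 4935 CPM in the class with a ratio of 2.14 in the cluster. Inside cluster 17, 4 of 11 leiomyoma genes were higher and 3 lower, with a median of 0.12. Matrix genes had a class median of -0.01 (11 of 27 higher, 5 lower, percentile 92.9), 0.39 relative to the shift, 0.55 inside cluster 0 and 0.34 inside cluster 17. Bgn stood at 17.9 and 156 CPM and Col1a1 at 46.3 and 177 CPM in the class, with ratios of 5.18 and 8.71 in cluster 0 and 4.91 and 2.36 in cluster 17. Thbs1 was 2.54-fold lower in the class, with ratios of 0.481 in cluster 0 and 1.16 in cluster 17.

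Genes of parturition and excitability had 1 of 14 members higher and 10 lower in the smooth muscle-like class (median -0.47, percentile 5.77, -0.37 with the member at 0 set to the bound). Oxtr, the oxytocin receptor gene, stood at 619 and 207 CPM, and Edn1 at 70.5 and 11.7 CPM, while Ptgs2 stood at 13.4 and 35.2 CPM. Relative to the shift the median was -0.06, and inside cluster 0 it was 0.54 with 6 of 10 higher, although Oxtr stayed lower with a ratio of 0.389 and Edn1 had only 3 and 10 UMIs. Inside cluster 17 the parturition median was -0.61, with 2 of 14 higher and 9 lower, and the ratio was 0.623 for Oxtr and 0.314 [0.114, 0.695] for Edn1. Progesterone-responsive genes had 1 of 17 higher and 9 lower, with a median of -0.54 (percentile 8.04), -0.14 relative to the shift, -0.08 inside cluster 0 and 0.15 inside cluster 17; Sgk1 stood at 1831 and 788 CPM in the class, with ratios of 1.26 in cluster 0 and 0.872 in cluster 17. Estrogen-responsive genes had a median of -0.29 (percentile 27.8), 0.11 relative to the shift, 0.12 inside cluster 0 and 0.074 inside cluster 17. Immediate early genes, which dissociation raises, had 2 of 21 higher and 10 lower and a median of -0.46 (percentile 14.2), against 0.44 inside cluster 0 and 0.52 inside cluster 17. Mitochondrially encoded genes, a sign of damaged cells, had a median of 0.68 (percentile 97.3) in the class, -0.03 inside cluster 0 and 0.44 inside cluster 17. Basement membrane genes (median -0.35, percentile 31.1) and TGF-beta response genes (median -0.38, percentile 42.3) were at 0.06 and 0.02 relative to the shift.

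Pgr (ENSMUSG00000031870, chromosome 9, 8899833 to 8968611) was lower in the cKO library in all 3 classes of the PR-Cre lineage. In the smooth muscle-like class it stood at 1415 CPM in the control and 346 CPM in the cKO library, a ratio of 0.244 [0.222, 0.269], which was 0.331 inside cluster 0 and 0.524 inside cluster 17. In the stromal-like class it stood at 761 and 418 CPM (ratio 0.549 [0.538, 0.561]) and in the epithelial-like class at 97.4 and 43.9 CPM (ratio 0.450 [0.405, 0.501]). In pericyte-like cells the values were 1015 and 495 CPM (ratio 0.487). Across the 9 clusters with at least 30 cells in both libraries the Pgr ratio ran from 0.281 to 0.611. After thinning, a Pgr UMI was found in 50.5% of control and 18.6% of cKO smooth muscle-like cells and in 47.2% and 31.2% of stromal-like cells, against 0.947% and 0.287% of T/NK-like cells. Unthinned, the smooth muscle-like shares were 66.5% and 31.0% at median depths of 1787 and 1643 UMIs. Because the Cre allele sits in Pgr, the Pgr level of a carrier can differ without any loss of Rest, and no library is labelled as Cre without the floxed gene.

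**Figure D3:**
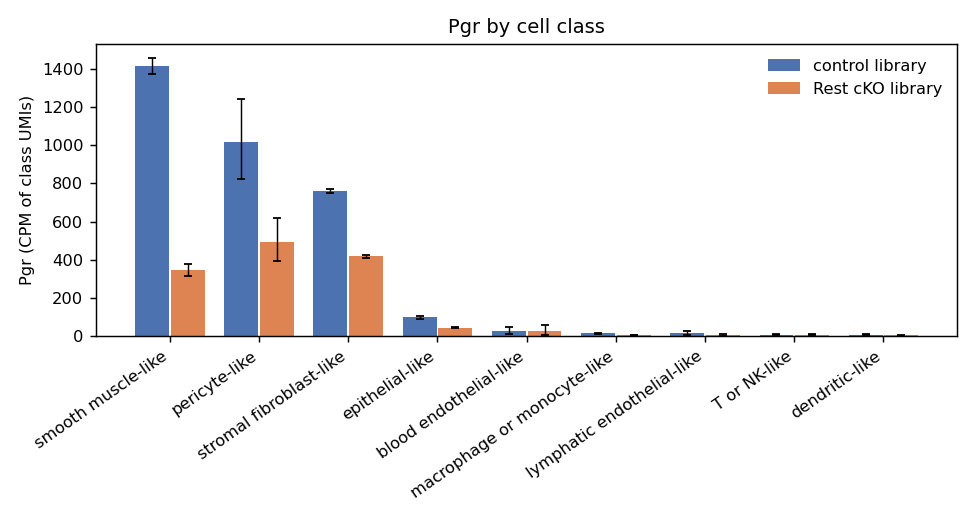
Level of Pgr (CPM, vertical axis) in 9 cell classes of the control and the cKO library, with exact 95% Poisson intervals for counting error. The bars of the cKO library are lower in the smooth muscle-like (1415 and 346 CPM), stromal-like (761 and 418 CPM) and epithelial-like (97.4 and 43.9 CPM) classes.

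The estrogen receptor gene Esr1 stood at 295 CPM in the control and 449 CPM in the cKO smooth muscle-like class (ratio 1.53 [1.37, 1.69]), at 149 and 113 CPM in the stromal-like class (ratio 0.760 [0.728, 0.793]) and at 128 and 163 CPM in the epithelial-like class (ratio 1.27 [1.18, 1.37]). With each library clustered alone the stromal-like log2 ratio of Esr1 was 0.019. The hormone receptor list as a whole had a median log2 ratio of 0.02 in the stromal-like class (percentile 72.9), with 3 of 8 members higher and 2 lower. Prlhr, the prolactin releasing hormone receptor gene (ENSMUSG00000045052, chromosome 19, 60466732 to 60468304), had 0 UMIs in the smooth muscle-like class of either library. It had 0 UMIs in the control and 1 in the cKO stromal-like class, and 0 and 10 in the epithelial-like class, where its cKO level of 0.542 CPM was close to the 0.557 CPM of free RNA and no difference was detectable at this depth.

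The epithelial-like class held clusters 10 (309 control and 81 cKO cells), 12 (98 and 263), 13 (55 and 246) and 21 (3 and 98). Cluster 12 supplied 67.7% of the control and 58.1% of the cKO UMIs, and cluster 21, led by the cornification genes Krt6a, Lor and Sprr2d, 2.44% and 28.5%. The highest ratios of the class included the neuronal genes Ptprn (0.613 and 184 CPM, ratio 301 [117, 1104]), Celf3 (1.23 and 119 CPM, ratio 97.3 [49.3, 226]), Ina (0.153 and 84.3 CPM, with 1 control UMI) and Chga (ENSMUSG00000021194, chromosome 12, 102554969 to 102565028), which had 0 control UMIs and 98.7 CPM in the cKO library, at least 215-fold higher. Serpina1e (11.9 and 400 CPM, ratio 33.5 [26.8, 42.4]) and Aoc1 (5.36 and 265 CPM, ratio 49.4 [35.5, 71.0]), both leading cluster 12, had ratios of 49.1 and 49.8 inside that cluster. Ly6d stood at 6.13 and 241 CPM, and Sprr2b and Sprr2d, which lead cluster 21, were 12.2-fold and 12.1-fold higher. Igkc stood at 3.06 and 207 CPM, with 98.5% of its cKO UMIs in 3 cells, and its log2 ratio was -1.93 when cells down to 500 UMIs were kept. Only 1 cKO cell of the class held 10 Igkc UMIs or more.

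Interferon genes were among the lowest of the epithelial-like class. Ifnb1, which encodes interferon beta (ENSMUSG00000048806, chromosome 4, 88522025 to 88522774), stood at 153 CPM in the control and 8.68 CPM in the cKO library, 17.6-fold lower [14.9, 20.9], with a UMI in 49 of 465 and 8 of 688 cells. Its UMIs were concentrated, with 51.3% of the control and 86.2% of the cKO UMIs in 3 cells each, which the interval does not cover. Cxcl10 stood at 663 and 64.2 CPM (10.3-fold lower [9.67, 11.0]), Rsad2 at 987 and 130 CPM (7.57-fold lower), Ifit3 at 287 and 30.3 CPM, Ifit2 at 95.3 and 5.42 CPM and Ifih1 at 221 and 28.3 CPM. Alox15 was 8.46-fold and Palld 10.7-fold lower, and Ccnb1ip1 and Rmrp, which lead cluster 10, were both 11.6-fold lower. Cluster 10 held 25.2% of the control and 1.52% of the cKO UMIs of the class. The class ratios of Ccnb1ip1 and Rmrp may follow that mix of clusters, which was not tested. Of the 16 interferon response genes 14 were lower and 1 higher, with a median of -1.30 (percentile 0) and sums of 4431 and 1320 CPM. The median was -1.45 in cluster 10, -1.14 in cluster 12 and 0.30 in cluster 13. Bst2 (239 and 283 CPM), whose log2 ratio was -0.23 in cluster 12, and Ifi27l2a (19.8 and 92.6 CPM) went against the rest.

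Cell cycle genes had 17 of 20 members higher and 0 lower in the cKO epithelial-like class, with a median of 1.14 (percentile 100) and sums of 310 and 930 CPM; Ube2c stood at 1.23 and 65.4 CPM and Mki67 at 0.919 and 37.9 CPM. Ube2c and Top2a lead cluster 13, and without that cluster the median was 0.37, with sums of 302 and 408 CPM over 410 control and 442 cKO cells. Inside cluster 13 it was 2.90, with sums of 493 and 4790 CPM, inside cluster 10 it was 0.77, and inside cluster 12 it was 0.25. Estrogen-responsive genes had 7 of 20 higher and 4 lower, with a median of 0.25 (percentile 92.8) and sums of 14279 and 28334 CPM, and Padi1 stood at 403 and 1052 CPM; the median was -0.092, 0.24 and 0.74 inside clusters 10, 12 and 13. Chemokine and cytokine genes had a median of -0.71 (6 of 20 higher, 13 lower, percentile 0), with Ccl5 43.6-fold lower, and medians of -0.61, -0.40 and -0.61 inside those clusters. TGF-beta response genes had 0 of 17 higher and 8 lower (median -0.45, percentile 0.04), with Tgfbi at 52.7 and 4.34 CPM, but the median was 0.035 in cluster 10 (4 higher, 6 lower), -0.43 in cluster 12 and -1.35 in cluster 13. Basement membrane genes had 1 of 11 higher and 9 lower (median -0.68, percentile 0), with Lama5, another gene leading cluster 10, at 629 and 212 CPM, and medians of -0.60, -0.39 and -1.17 inside clusters 10, 12 and 13. Immediate early genes had a median of -0.59 (0 of 21 higher, 11 lower, percentile 0.01), but 0.16 inside cluster 10 (4 higher, 4 lower), -0.28 inside cluster 12 and -0.59 inside cluster 13. Luminal epithelium genes had a median of 0.14 (4 of 9 higher, 1 lower, 0.08 with zeros at the bound, percentile 82.1). Of the 8 measured glandular epithelium genes 6 were lower and 2 higher, with a median of -0.29 (-0.27 with zeros at the bound, percentile 0.52), and the gland products Spink1 (41.5 CPM in the control, 0 UMIs in the cKO library, at least 255-fold lower) and Prss29 (17.5 CPM and 0 UMIs, at least 107-fold lower) were the lowest.

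Macrophage-like cells of the cKO library held fewer transcripts of the interferon-gamma chemokine gene Cxcl9 (174 and 25.4 CPM) and of Cxcl13 (92.8 and 2.90 CPM, 32.0-fold lower [20.4, 53.1]), Hes1 (124 and 12.5 CPM), Serpina3f (75.3 and 10.7 CPM) and Mmp13 (1095 and 287 CPM). Their MHC class II genes had 0 of 7 higher and 4 lower, with a median of -0.69 (percentile 0); H2-Eb1 stood at 3971 and 1920 CPM and H2-Aa at 5870 and 3029 CPM. Hypoxia and glycolysis genes had 9 of 16 higher and 0 lower, a median of 0.68 (percentile 100), with Bnip3 at 56.3 and 154 CPM and Ankrd37 at 6.87 and 39.9 CPM, the last with a log2 ratio of -0.20 inside cluster 2. Chemokine and cytokine genes had 2 of 19 higher and 10 lower and a median of -0.38 (percentile 0), with Ccl8 at 2276 and 920 CPM. Saa3 stood at 4.12 and 91.5 CPM (ratio 22.2 [13.4, 39.9]), and Ccl6, which leads cluster 16, was 6.77-fold higher. Igkc (544 CPM in the cKO library), Ighg2c (349 CPM) and Jchain (83.3 CPM) had high ratios as well, but 3 cells held 99.2%, 100% and 98.6% of their UMIs. For each gene only 1 cKO cell of the class held 10 UMIs or more. The class consisted of clusters 2 (290 control and 522 cKO cells) and 16 (51 and 234). Cluster 16 held 19.7% of the control and 40.8% of the cKO UMIs of the class, and Ccl8 is a leading gene of cluster 2. The list values above are for the whole class, so they may reflect this mix of clusters.

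T/NK-like cells of the cKO library held more transcripts of granzymes: Gzmb, which leads cluster 3, stood at 236 and 711 CPM, Gzmc at 58.3 and 224 CPM and Gzmf at 21.8 and 85.7 CPM. Hspa1b (52.3 and 260 CPM, ratio 4.96 [4.30, 5.74]) and Ifi203 (57.2 and 132 CPM) were the other genes with the highest ratios. The lowest were Pclaf (102 and 17.0 CPM), Hist1h2ap (65.8 and 8.62 CPM), Mki67 (143 and 37.6 CPM), Stmn1 (211 and 59.3 CPM) and Top2a (185 and 59.6 CPM), all of which lead cluster 26, with 26 control and 3 cKO cells. Cell cycle genes had 0 of 20 higher and 17 lower and a median of -0.94 (percentile 0), but -0.033 inside cluster 3 and 0.069 with a limit of 10% mitochondrial UMIs, so the difference rests on cluster 26. MHC class II genes had 0 of 6 higher and 5 lower, with a median of -1.38 (percentile 0), and Cd74 stood at 192 and 31.1 CPM. Inside clusters 3, 15 and 18 the Cd74 ratio was 0.535, 0.0823 and 0.0418, and the sum of the list in free RNA was 2438 CPM in the control and 1429 CPM in the cKO library. Dendritic-like cells, all in cluster 8 (224 control and 226 cKO cells), expressed 14.7-fold less [9.57, 23.7] of the interleukin-12 subunit gene Il12b, at 140 and 9.56 CPM. Scd1 was 5.85-fold lower, Adh7 4.63-fold, Serpinb9b 4.03-fold and Gclc 3.09-fold lower. Hypoxia and glycolysis genes had 9 of 16 higher and 1 lower there, with a median of 0.51 (percentile 100), including Tpi1 (67.0 and 194 CPM), and Hmgcs1, Slc16a3, Pou2f2 and Gpx1 were between 2.40-fold and 2.98-fold higher.

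The remaining lists checked dissociation, blood and nerve tissue. Heat shock genes had a median log2 ratio of -0.09 in the stromal-like class (0 of 14 higher, 1 lower, percentile 53.7), 0.37 in the macrophage-like class (6 higher, 0 lower, percentile 99.97) and 0.16 in the T/NK-like class (5 higher, 0 lower, percentile 99.77), and immediate early genes -0.27 in the stromal-like class (0 of 21 higher, 2 lower, percentile 6.05). Hemoglobin genes were close to unmeasured, with 1 of 4 reaching 10 UMIs in the stromal-like class. Genes of neurons and glia had 2 of 7 higher and 4 lower in the stromal-like class, with a median of -0.06 (percentile 5.94), while in the smooth muscle-like class 2 of 3 were higher and 1 lower, with a median of 1.23 (percentile 99.97), Rbfox3 standing at 4.57 and 55.1 CPM.

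**Figure D4:**
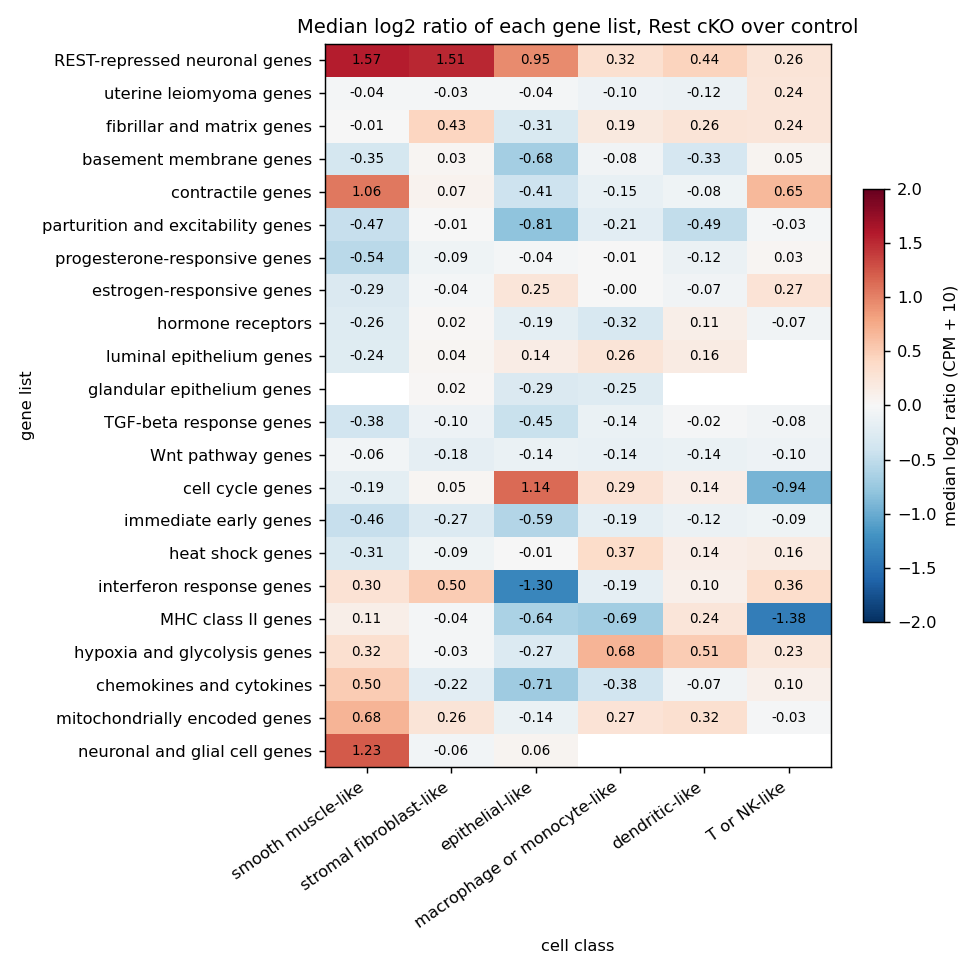
Median log2 ratio (cKO over control) of each gene list (vertical axis) in the 6 compared cell classes (horizontal axis), for lists with at least 3 measured members; color gives the median. The REST-repressed list has the highest medians, 1.57 in the smooth muscle-like and 1.51 in the stromal-like class, and the interferon response list -1.30 in the epithelial-like class.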

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

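Of the explanations weighed here, the 2 for the REST-repressed list in immune cells and the one of the cluster led by Top2a were written before their values were computed; the others were chosen after seeing the data, as were the comparisons with the control level and inside clusters for the explanations written before.

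Cell cycle genes went in opposite directions between classes: the median log2 ratio was 1.14 in the epithelial-like class and 0.29 in the macrophage-like class, but -0.94 in the T/NK-like class. The last value rests on a cluster of 26 control and 3 cKO cells and became 0.069, 0.044 and 0.11 under other settings. Interferon response genes differed in direction too, with 0.50 in the stromal-like and -1.30 in the epithelial-like class. No difference between classes was tested, since each rests on 1 library per genotype. In barcodes of 1 to 100 UMIs, which no comparison of cells uses, the REST-repressed list summed to 1171 CPM in the cKO library against 69.2 CPM in the control.

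Pgr was lower in the smooth muscle-like, stromal-like and epithelial-like classes of the cKO library. A different mix of clusters would leave the ratio near 1 inside clusters. It lay below 1, upper bound included, in 9 of 9 clusters with at least 30 cells in both libraries. That speaks against the mix of clusters as the whole cause only if each cluster held the same kinds of cell in both libraries. Clusters differed inside in other genes too, such as matrix genes in the stromal-like cluster 4 (3473 and 14160 CPM). A different mix of cells inside clusters is therefore not excluded. Clusters 5 and 7, with 40.0% and 32.2% of the stromal-like cKO UMIs, and the epithelial-like cluster 21 were not covered. The smooth muscle-like class ratio of 0.244 lay below those of its clusters (0.331 and 0.524), so the mix contributes there. Free RNA is unlikely to supply the Pgr UMIs of the smooth muscle-like and stromal-like classes, whose control levels were 406% and 218% of the free-RNA level. The epithelial-like level was 27.9% of it, 6.95 times the highest level of an immune class (macrophage-like, 4.02%). Blood endothelial-like cells, however, stood at 7.20%. Pgr in free RNA was itself lower in the cKO library, at 349 and 138 CPM, so free RNA was not set aside for the epithelial-like class. The Cre knock-in may itself remove the transcript of 1 Pgr allele, for which a ratio near 0.5 would be looked for in every class. The class ratio was 0.549 in stromal-like, 0.450 in epithelial-like and 0.487 in pericyte-like cells. It was lower in the larger smooth muscle-like cluster (0.331) and in the stromal-like cluster 14 (0.281). The allele and the loss of Rest, the biological explanation, cannot be told apart without a Cre-only control. Estrous stage is not given in the labels and was not weighed for Pgr. Stage could differ between the pools, and Pgr is itself on the estrogen-responsive list.

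REST-repressed genes were also higher in immune classes, where PR-Cre is not known to act. Free RNA from uterine cells could hold much of it: relative to the free level, the list stood at most 2.54 times (T/NK-like) and at least 1.07 times (macrophage-like) as high as stromal marker genes, inside the 3-fold bound set beforehand. Part of the T/NK-like level was present in the control too, as for L1cam at 30.8 and 30.1 CPM. The part of the list above the control, relative to that of free RNA, was 1.40 times as high as all stromal markers together in T/NK-like cells. It was 1.14 times as high in dendritic-like and 0.934 times as high in macrophage-like cells. Against Dcn alone it was 4.22% against 2.60% in T/NK-like, 3.65% against 1.56% in dendritic-like and 5.76% against 3.14% in macrophage-like cells. The bound set beforehand was meant to exclude lost repression within immune cells, the biological explanation, but wrongly so. That free RNA can hold the list within 3-fold does not show that it holds all of it. The excess of 1.40 in T/NK-like cells leaves part of the list uncovered there. Against Dcn alone part is uncovered in the dendritic-like and macrophage-like cells too, so this explanation stays open.

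Cell cycle genes were higher in the cKO epithelial-like class. Cervical or vaginal epithelium in 1 dissection could be a cause: without the cornified-like cluster 21 the median was 1.37, which sets aside the cornified cells alone, not other cells of such tissue. A larger share of cluster 13, led by Ube2c and Top2a, met its bound, since without that cluster the median was 0.37, under 1.5-fold, but that bound was too weak. A share alone would leave levels inside clusters alike if each cluster held the same kinds of cell in both libraries. The median was 2.90 inside cluster 13 (20 of 20 higher, 493 and 4790 CPM) and 0.77 inside cluster 10 (6 of 9 higher). However, cluster 13 differed between the libraries in contractile genes too (3314 and 1043 CPM). A different mix of cells inside a cluster could give such medians, so they cannot exclude share as the whole cause. Estrous stage could differ between the pools, and the estrogen-responsive list with its median of 0.25 cannot separate stage from genotype, the biological explanation, with 1 library each.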

How the results depend on the processing

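Under the alternatives, 1504 of the values of single genes stayed inside the interval of the main value, 848 moved outside it and 26 changed direction. A change of direction was counted only where that interval lay entirely above or below no difference. Changes of sign by other values are not among them. For gene lists the numbers were 799, 56 and 11, and for shares of cells 104, 18 and 5. The interval of a gene covers counting error. That of a list covers the spread of its members, except for the shortest lists, where it covers counting error. That of a share difference was made from the outer bounds of the intervals of both libraries. The numbers for genes, lists and shares are therefore not comparable, and those for lists do not show that lists are more stable. No paired analysis was possible because each genotype has 1 library. The cause of the changes below was not tested, except where fewer cells or another scale account for them by construction. Restricting a class to its best shared cluster, to clusters by Hand2 or to clusters without cornification, counting shallow clusters with the class of their markers, and clustering without the REST-repressed genes were chosen after seeing the data; under the last, every result that answers a comparison stayed the same.

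Differences of shares are in percentage points, and several came with more unnamed cells than the 5.29% and 5.21% of the main setting. With cells from 500 UMIs and 250 genes, the stromal-like difference became 2.42, the epithelial-like -2.18, the smooth muscle-like -0.046 and the neutrophil-like 5.49, with 24.7% of the control and 15.7% of the cKO cells unnamed. With a minimum of 2000 UMIs, the smooth muscle-like difference was -5.08 and the stromal-like -10.6. The stromal-like difference was also -10.4 at 10% mitochondrial UMIs, -9.60 without doublet removal and -9.48 at resolution 0.5, settings that left 17.2% to 17.7% of the cKO cells unnamed. With each library clustered alone it was 13.8, with -3.07 for macrophage-like, 3.49 for dendritic-like and 3.77 for all immune cells. Among non-immune cells it was 2.93, and the epithelial-like difference 3.32.

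The remaining values are log2 ratios. With each library clustered alone, stromal-like Esr1 became 0.019, Wnt4 0.16 and the Wnt list 0.018. In the best shared cluster of the smooth muscle-like class, Kcnq1ot1 was 0.51, Carmn 0.040, Edn1 0.48 and Sgk1 0.33, of which Carmn and Edn1 rest on 10 UMIs or fewer per library and, like Kcnq1ot1, were lower in the other cluster. In the best shared cluster the parturition list was 0.54, immediate early 0.44, mitochondrial -0.026, basement membrane 0.071 and contractile 0.63. In the best shared clusters of other classes, stromal-like Ctla2a was 1.20, Rest -0.0026 and the interferon list 0.14, epithelial-like Bst2 -0.23 and the cell cycle list 0.25, T/NK-like Hist1h2ap 0.092, Top2a 0.14 and the cell cycle list -0.033, and macrophage-like Ankrd37 -0.20. In stromal-like clusters with more Hand2, Cxcl5 was 2.55, Ccl2 1.03, Cxcl2 0.41 and Lif 0.14; in those with less, Ccl11 was -0.26 and the interferon list 0.10. Relative to the general shift, smooth muscle-like Rest was 0.17 and the basement membrane list 0.058.

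Averaged over clusters, the smooth muscle-like immediate early list was 0.49 and the contractile list 0.52, the stromal-like Wnt list 0.16 and interferon list 0.79, the T/NK-like cell cycle list 0.11 and the epithelial-like interferon list -0.93. T/NK-like cycling values turned with the cluster of 26 control cells: at 10% mitochondrial UMIs Pclaf was 0.0060, Hist1h2ap 0.26, Mki67 0.46, Top2a 0.42 and the cell cycle list 0.069, and at resolution 0.5 Hist1h2ap was 0.30, Mki67 0.46, Top2a 0.44 and the list 0.044. That list was -1.53 with cells from 500 UMIs, and epithelial-like Igkc was -1.93 there.

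Pseudocounts of 1 and 50 CPM scaled the medians as built. The REST-repressed list was 3.72 and 0.53 in the smooth muscle-like, 3.94 and 0.52 in the stromal-like and 2.29 and 0.25 in the epithelial-like class, and 2.80 in the smooth muscle-like class with a list minimum of 50 UMIs. The stromal-like interferon list was 0.99 and 0.16, the epithelial-like cell cycle list 2.58 and 0.37, and the T/NK-like one -1.60 and -0.46. The epithelial-like interferon list was -0.83 at 50 CPM. Depth limits the smooth muscle-like class most, with medians of 1787 and 1643 UMIs per cell.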

Other observations

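REST-repressed genes were also measured in classes too small to compare in full. In pericyte-like cells (36 control and 52 cKO) all members of the list together stood at 173 CPM in the control and 2682 CPM in the cKO library, a ratio of 15.5 [9.44, 27.4], close to the 12.4 [11.2, 13.7] of the smooth muscle-like and the 15.2 [13.8, 16.7] of the epithelial-like class, and below the 48.0 [46.0, 50.2] of the stromal-like class. In blood endothelial-like cells (50 and 41) the list stood at 54.8 and 219 CPM (ratio 3.99 [2.38, 6.85]), and the cKO level was 18.7% of that of free RNA, against 1.07% for Dcn, 3.10% for Pdgfra, 3.33% for Lum and 18.3% for all stromal markers together. Lymphatic endothelial-like cells (43 and 68) held 96.6 and 127 CPM (ratio 1.31 [1.01, 1.72]), and mesothelial-like cells (15 and 64) 136 and 132 CPM (ratio 0.968 [0.684, 1.41]), so the mesothelial-like difference was not detectable at this depth.

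Cluster 25, left unnamed because epithelial and stromal markers were both high, held 53 control cells and 0 cKO cells (1.27% of the control). It was led by Ifnb1, Ifit2, Rsad2 and Cxcl10, and Ifnb1 stood at 450 CPM in it. Cluster 20, led by mast cell genes such as Cma1 and Cpa3 and unnamed because B or plasma cell markers were nearly as high, held 51 control and 55 cKO cells. Cluster 11, shallow and nearest to stromal markers, held 117 and 248 cells. In T/NK-like cells, contractile genes had 10 of 16 members higher and 0 lower with a median log2 ratio of 0.65 (percentile 100). Their sum in free RNA was 5575 CPM in the control and 5123 CPM in the cKO library.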
